A study of Mus musculus with 6 samples.

How the data were processed

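Total RNA was extracted from the back skin of 3 caNrf2 and 3 control mice, 1 array per mouse. Per the labels' protocols, the animals were females of 1 litter, the skin was snap frozen, and biotinylated cRNA was prepared from 2 µg of RNA with a one-cycle labelling kit for Affymetrix arrays. The deposited table holds 1 intensity per probe set and array, on a linear scale, and per the submitters' processing notes these values were made with RMA, which subtracts background, normalises arrays by quantiles and summarises the probes of a set. The version of RMA, its software and any filter are not given in the sources used here. RMA makes the array distributions nearly equal, so a shift shared by most genes would not be seen, and it compresses folds of genes close to background. Scanner files were not used here. Columns of other series numbered 0.

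The linear intensities were converted to log2, since the test had been planned on log2 values. Of 45101 probe sets, 64 Affymetrix controls were left out of the fits, which left 45037. The platform annotation gave 1 gene symbol for 34945 of these, several for 932 and none for 9160, and only probe sets with 1 symbol were named. For 34741 the gene identifier was found in a table of reference genes, assembly GRCm38.p6, which changed 0 symbols; this table also gave the order of genes along chromosomes, and no coordinate from it is reported. For each of 18193 genes the probe set with the highest mean over the 6 arrays was used. Where a gene has more than 1 probe set these can disagree: of 30 called genes with several, 2 had a probe set of opposite sign.

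Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, no block and no covariate, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. Replicates were separate animals. Fold changes are caNrf2 over control, and SE and 95% intervals come from the same fit. Gene lists, 39 in number, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. They covered Nrf2 targets, the cornified envelope, the barrier, keratinocyte states, growth factors and cytokines, other skin cell types, and signs of stress or handling. Symbols of some members were not measured, and counts refer to measured members. Array controls were compared with exact two-sided permutation tests over the 6 arrays.

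The genes named were fixed by rule before the data were examined: the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, of which only 5 falls existed, a set named in advance (Nfe2l2, Keap1, Nqo1, Gclc, Gclm, Srxn1, Slc7a11, Slpi, Sprr2d, Epgn and Elovl3), and up to 4 members of each list with the smallest p. Other names are said to have been chosen later.

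The fit was also tested on simulated arrays, with the control means of the 18193 genes and with variances drawn from the prior that limma estimated in the real comparison. It recovered 85.1% of 67 genes changed 1.5-fold and 100% of 67 changed 2-fold and 66 changed 4-fold. Of its calls 5% were false, and it made 0 calls when nothing was changed. Genes varied independently in this simulation, as many fell as rose, and more changed at least 2-fold than were called at that size in the skin. The rates may therefore not hold for the real comparison. Alternatives were a replicate block, median centring, a further quantile normalisation, a filter on low values, the mean of all probe sets of a gene, an intensity trend, robust eBayes, array weights, a test against a fold of 1.2 (treat), camera on ranks, and leaving out each array in turn. Cyclic loess normalisation was added after the data had been seen. Random gene placements and level-matched random lists used 10000 draws.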

Results

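Gene expression was measured in the whole back skin of 6 female mice of 1 litter at postnatal day 2.5. Three-prime expression arrays for the mouse transcriptome were used, with 1 array per animal. In 3 mice a constitutively active form of the transcription factor Nrf2 (caNrf2), which switches on antioxidant and detoxification genes, was combined with a Cre recombinase driven by the keratin 5 promoter, which is active in basal keratinocytes. The other 3 mice served as controls and are labelled tg/wt, read here as carrying the Cre transgene alone. All were of a mixed FVB/N and C57BL/6 background. The comparison asks which transcripts differ in the skin of mice with an always active Nrf2 in keratinocytes. Array medians were alike, between 80.9 and 82.1 intensity units. Upper quartiles were 330.7 to 333.3 on the control arrays and 332.5, 344.5 and 342 on caNrf2 arrays 1 to 3. Lower quartiles were 24.6 to 24.9 and, in the same order, 24.5, 23.5 and 23.9. Across probe sets, arrays correlated at 0.9978 to 0.9980 among controls, 0.9961 to 0.9969 among caNrf2 arrays and 0.9961 to 0.9972 between groups. The control arrays were thus more alike than the caNrf2 arrays. The number of arrays, 3 per group, limits the precision.

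The gene altered by the transgene was examined first. The probe set of Nfe2l2, which encodes Nrf2, measured 9.39 ± 0.03 in control and 9.81 ± 0.09 in caNrf2 skin (log2 intensity, mean ± SD, n = 3). All caNrf2 values lay above all control values, but the log2 difference of 0.41 ± 0.07 (SE) missed the threshold (adjusted p = 0.0539). A second, dimmer Nfe2l2 probe set differed by 0.24. Whether these probes match the transgene was not analysed here, so the values check the labels only in part. Keap1, the inhibitor of Nrf2, differed by 0.28 ± 0.08 (adjusted p = 0.329). Xist lay between 12.33 and 12.58 on every array and 3 Y-linked genes between 2.94 and 3.95, as the female label requires. The Y-linked values also show what level a silent gene has on these arrays.

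Few genes differed between caNrf2 and control skin, and nearly all of these were higher in caNrf2 skin. Of 18193 genes tested, 63 rose and 5 fell in caNrf2 skin (limma, Benjamini-Hochberg adjusted p under 0.05). A change of at least 1.5-fold was seen for 44 of the risen and 3 of the fallen genes, and 20 genes rose at least 2-fold while none of the called genes fell that far. The 12 largest rises included the glutathione S-transferases Gsta3, Gsta4 and Gstm1 and the transporters Abcc3 and Abcc4. Of the 68 called genes, 29 belonged to lists of known Nrf2 targets that hold 60 measured genes. At an unadjusted p under 0.05 there were 1471 genes, of which 594 were higher. All 68 called genes separated the groups without overlap, as did 13.1% of all genes, where chance gives 10%.

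Gsta3, an alpha-class glutathione S-transferase, rose the most on the probe set used. It went from 17.4 ± 1.07 intensity units in control to 572 ± 19.7 in caNrf2 skin (mean ± SD, n = 3), a 32.9-fold difference (95% interval 29.3 to 36.9; adjusted p = 1.34e-10). Its control level of 4.12 on the log2 scale was close to that of the silent Y-linked genes, so the fold is uncertain, and its second probe set rose by 2.05 (log2). With the mean of both probe sets it rose by 3.54 and ranked below Gpx2 and Nqo1. Gpx2, a glutathione peroxidase of epithelia, rose 13.1-fold (log2 3.71 ± 0.07 SE, adjusted p = 1.54e-09). Nqo1, a quinone reductase and a standard marker of Nrf2 activity, rose 12.2-fold (3.61 ± 0.13, adjusted p = 2.70e-07). Srxn1, which repairs oxidised peroxiredoxins, rose 5.81-fold. Adh7, an alcohol dehydrogenase that also oxidises retinol, rose 5.13-fold, and Pir, which encodes the iron-binding nuclear protein pirin, rose 4.55-fold. Gsta4 rose 4.26-fold, the aldehyde dehydrogenase Aldh3a1 4.11-fold and the multidrug resistance transporter Abcc3 3.64-fold. Gstm1, Cbr3 and Abcc4 completed the 12 largest rises at 3.16-fold, 2.96-fold and 2.82-fold. The probe sets of Srxn1 and Gstm1 are of kinds that can also bind related transcripts.

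**Figure D1:**
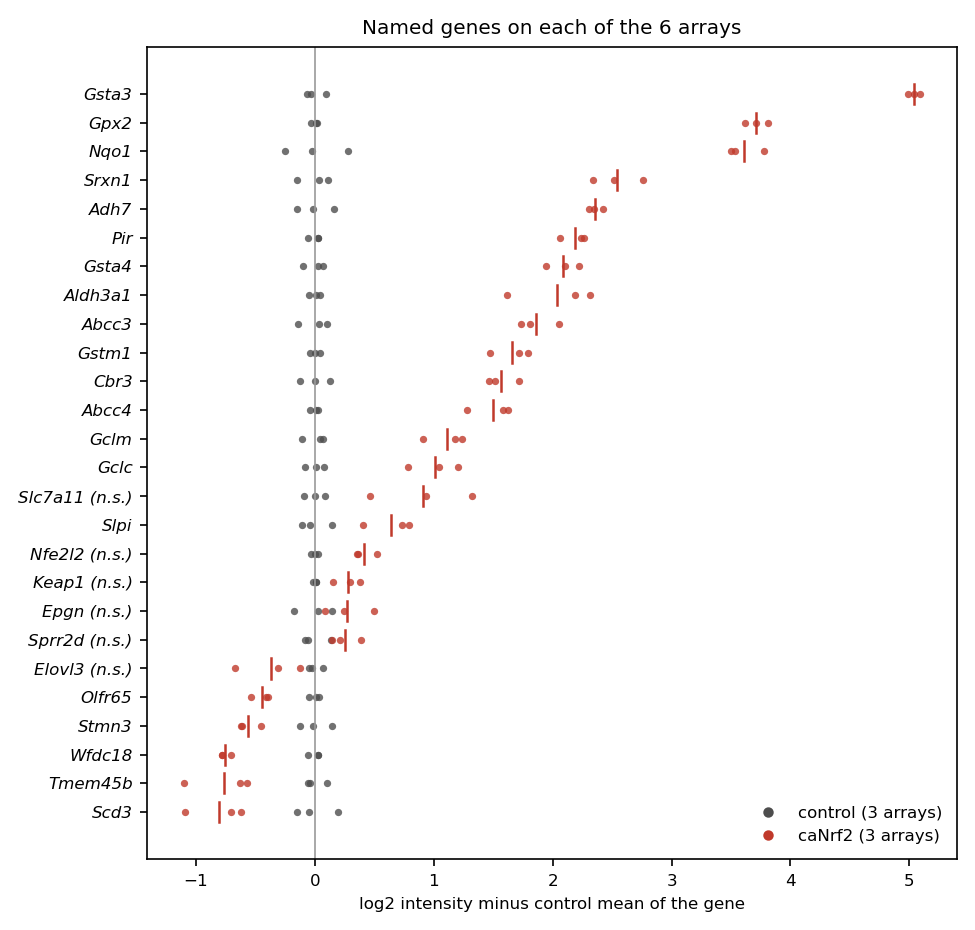
Log2 intensity of the named genes on each of the 6 arrays, minus the control mean of the gene, on the horizontal axis, with 1 gene per line. Grey points are control arrays, red points caNrf2 arrays, red bars their mean, and n.s. marks genes that missed the adjusted p threshold; Gsta3 lies 5.04 above its control mean and Scd3 0.81 below its own (-0.81).

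Each of the 5 lists of Nrf2 targets, fixed before the data were examined, held risen genes and none that fell. Of 27 measured detoxification genes 16 rose and none fell, with a median log2 difference of 0.57; adjusted over the list alone, 18 rose. Of 10 genes of glutathione synthesis and use 5 rose, and 8 when adjusted over the list alone, with a median of 0.77. They included both subunits of glutamate-cysteine ligase, the rate-limiting enzyme of glutathione synthesis, with Gclc at 2.01-fold and Gclm at 2.16-fold, and glutathione synthetase, Gss, at 1.81-fold. Slc7a11, the cystine transporter of this list, differed by 0.91 ± 0.17 and missed the threshold (adjusted p = 0.0729), while its second probe set, at the level of silent genes in control skin, passed in the fit of all probe sets (2.00, adjusted p = 6.71e-06). Of 7 thioredoxin and peroxiredoxin genes 3 rose (4 over the list alone, median 0.41), and the median was 0.12 when all probe sets of a gene were averaged. The risen genes were Srxn1, thioredoxin reductase Txnrd1 at 1.71-fold and catalase, Cat, at 1.56-fold. Of 6 genes that supply NADPH 3 rose (4 over the list alone, median 0.45), with Pgd at 1.92-fold, malic enzyme Me1 at 1.54-fold and Taldo1 at 1.47-fold, a call lost when some single arrays were left out. In the iron, haem and stress list only Osgin1 at 2.32-fold and biliverdin reductase Blvrb at 2.00-fold rose among 10 genes (2 over the list alone, median 0.18), and haem oxygenase Hmox1 differed by only 0.24 ± 0.10 (adjusted p = 0.592).

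Each of these 5 lists passed camera, a test of a list against all other genes, with a preset correlation of 0.01 (adjusted p from 1.05e-44 for detoxification to 7.16e-08 for iron, haem and stress). None passed with an estimated correlation, where adjusted p = 0.0597 for detoxification, 0.0634 for both the glutathione and the thioredoxin list, 0.147 for NADPH and 0.253 for iron, haem and stress. With fry, which tests whether the members of a list move on balance in 1 direction, the first 4 passed, with adjusted p between 0.000523 for detoxification and 0.00242 for NADPH, and iron, haem and stress did not (0.0637). The aryl hydrocarbon receptor list passed camera as well (adjusted p = 0.0206; 0.399 with an estimated correlation), but its median was 0.01 and its only 2 risen members were Nqo1 and Aldh3a1, which are Nrf2 targets too; adjusted over the list alone, 2 were higher and 1 lower. Cyp1a1, the classical target of that receptor, differed by -0.35 ± 0.11 (adjusted p = 0.416).

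Measured transcripts of the cornified envelope differed little in whole skin at this age, and the envelope itself was not examined. Measurements covered 8 of the 15 listed small proline-rich genes and 15 of the 20 listed late cornified envelope genes. None of 15 late cornified envelope genes (median 0.02), 21 other cornification genes (median 0.03) or 8 small proline-rich protein genes (median 0.00) passed the threshold, and none of these 3 lists passed camera. Adjusted over the list alone, 1 small proline-rich gene passed, Sprr2h, at 0.30 ± 0.07. Sprr2d differed by 0.25 ± 0.09 (adjusted p = 0.504) and Sprr1b by -0.50 ± 0.18 (adjusted p = 0.506). Among 22 epidermal proteases and inhibitors the protease inhibitor Slpi rose 1.56-fold (0.64 ± 0.11, adjusted p = 0.0422), a call that was lost when any 1 array but caNrf2 3 was left out, with adjusted p up to 0.233. Adjusted over the list alone, 3 were higher. This list had a median of 0.07 and passed camera (adjusted p = 0.0206), but not with an estimated correlation (adjusted p = 0.253). The 31 genes of barrier lipid synthesis held no called gene (1 higher when adjusted over the list alone), a median of 0.07 and a camera shift upward (adjusted p = 0.00182; 0.211 with an estimated correlation). Elovl3, an elongase of very long chain fatty acids in that list, differed the other way, by -0.37 ± 0.12 (adjusted p = 0.442).

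All 6 measured ligands of the epidermal growth factor family were higher in caNrf2 skin, by a median of 0.22, but none passed the threshold over all genes. Adjusted over the list alone 2 rose, Btc by 0.45 ± 0.11 and Ereg by 0.27 ± 0.09. Epgn, which encodes epigen, differed by 0.28 ± 0.12 (adjusted p = 0.588). The list passed camera (adjusted p = 0.00127; 0.147 with an estimated correlation). Among stress keratins and alarmins Il1f9, which encodes interleukin 36 gamma, rose 1.95-fold (0.96 ± 0.07, adjusted p = 0.000112), and Krt16 differed by 0.75 ± 0.15 (adjusted p = 0.105). Adjusted over the list alone, 2 of its 13 genes were higher. The median of that list was 0.01 and it did not pass camera, nor did the cytokines and chemokines (median -0.02), the interferon response (-0.14), the unfolded protein response (0.04) or the cell cycle genes (0.00). Fry in either direction, where members may rise or fall, called 11 lists. The stress keratins and alarmins were among them (adjusted p = 7.62e-05), and the others named here were not. Cytokine and interferon genes were dim, with mean levels of 5.59 and 5.88 (log2), below the 6.34 of the median probe set.

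Keratinocyte markers were close to equal. The 11 basal markers were all higher by small amounts, between 0.03 and 0.15, with a median of 0.06 (camera adjusted p = 0.0206; 0.336 with an estimated correlation). Suprabasal markers had a median of 0.05 (1 higher when adjusted over the list alone) and upper follicle markers 0.05, and neither list passed camera. Sebaceous gland genes had a median of -0.06 and did not pass. They held the only member of any list that fell over all genes, the desaturase Scd3, which fell by 0.81 ± 0.13 (0.57 of the control level, adjusted p = 0.0294); adjusted over the list alone, 1 was lower. The hair follicle keratins and shaft genes had a median of -0.06 and did not pass camera, but this result hung on single arrays. Their median was -0.24 and called lower without caNrf2 array 1, and 0.09 and called higher without caNrf2 array 3.

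**Figure D2:**
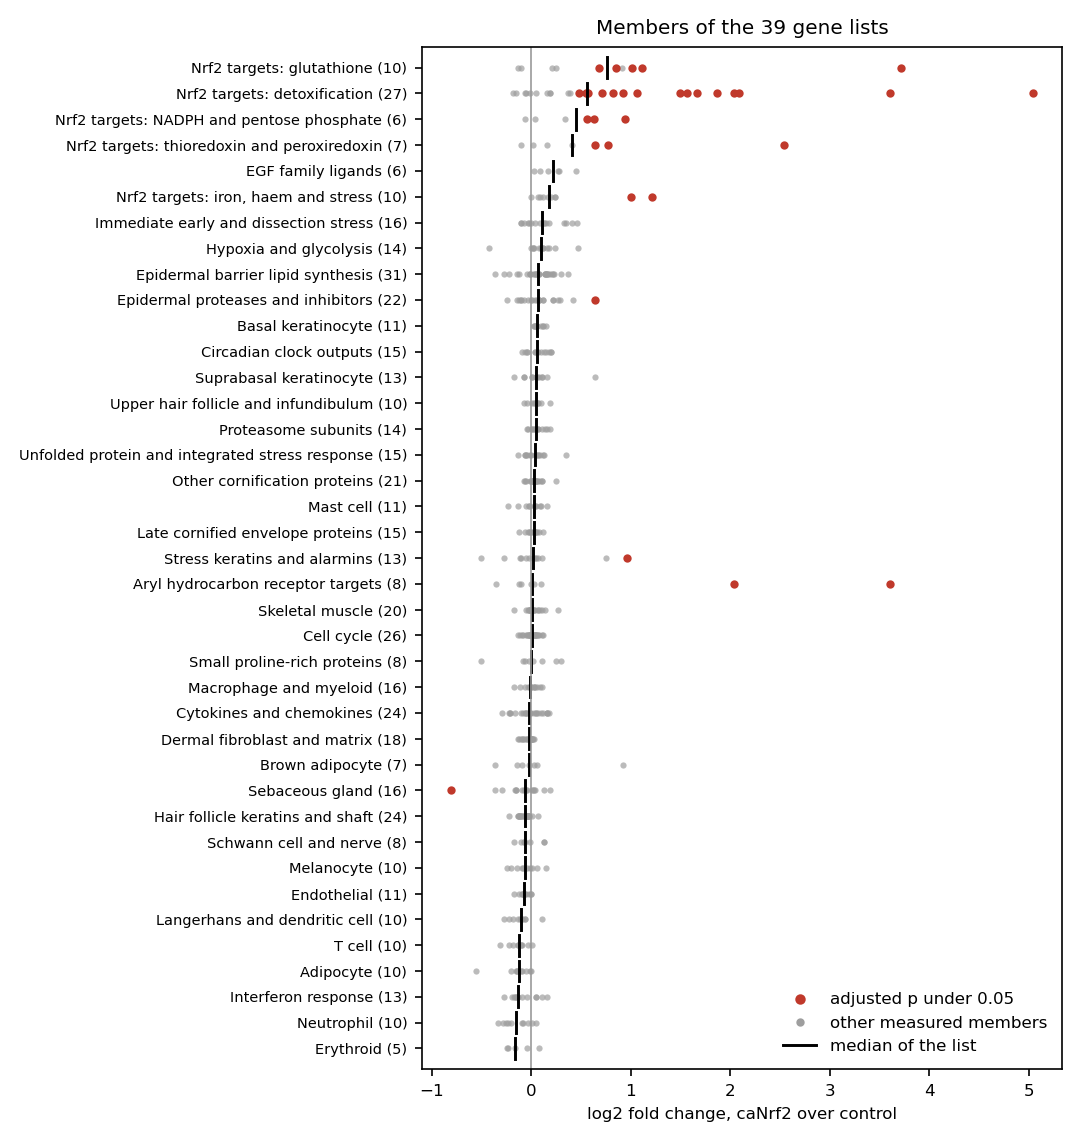
Log2 fold change of caNrf2 over control for every measured member of the 39 gene lists, with the number of measured members in brackets. Red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians; the medians of the Nrf2 target lists run from 0.18 to 0.77, and those of all other lists from -0.16 to 0.22.

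Markers of other cell types in the skin moved little, and none of their genes passed the threshold over all genes. The lists lower in camera were 4, each with no called gene. Adipocyte markers had a median of -0.12 (adjusted p = 0.0181; 0.399 with an estimated correlation), with Pck1 at -0.55 ± 0.10 (adjusted p = 0.0666; adjusted over the list alone, 1 gene was lower). Neutrophil markers had a median of -0.15 (0.0206; 0.378 with an estimated correlation), Langerhans and dendritic cell markers -0.10 (0.0226; 0.336) and T cell markers -0.12 (0.0162; 0.336). The neutrophil and T cell lists had mean levels of 5.19 and 6.11 (log2), below the 6.34 of the median probe set. Each of these 4 lists lost its call when some single array was left out. Lists that did not pass were those of dermal fibroblasts and matrix (median -0.02), brown adipocytes (-0.02), skeletal muscle (0.01), erythroid cells (-0.16, with 1 gene lower when adjusted over the list alone), endothelium (-0.08), macrophages (-0.01), mast cells (0.03), melanocytes (-0.07) and Schwann cells and nerve (-0.06). Lists that bear on the handling of the tissue were shifted in camera too. Immediate early genes had a median of 0.11 (camera adjusted p = 0.0107; 0.456 with an estimated correlation), hypoxia and glycolysis genes 0.10 (0.00826; 0.336; adjusted over the list alone, 1 higher and 1 lower), and circadian clock outputs 0.06 (0.0440; 0.336). Relative to the control mean, the immediate early genes averaged 0.21, 0.16 and -0.002 on the 3 caNrf2 arrays, so the third showed no shift. Proteasome subunits had a median of 0.05 (camera adjusted p = 0.0294; 0.621 with an estimated correlation). Of the 13 lists outside the Nrf2 targets that passed camera, higher or lower, 7 kept the call without caNrf2 array 2. Without control array 1 it was 11, the most for any array left out.

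Genes outside every list made up 36 of the 68 called genes, and several of those named next were chosen after their values were seen. Besides Adh7 and Pir, Gstm6 rose 2.70-fold and Mafg, which encodes a small Maf partner of Nrf2 on DNA, rose 1.56-fold. H60c, which encodes a skin ligand of the lymphocyte receptor NKG2D, rose 1.70-fold. The prostaglandin synthase Ptgs2 rose 2.10-fold and the inflammatory caspase Casp1 1.47-fold, but both lost the call when some single arrays were left out, and a second Ptgs2 probe set differed by only 0.31. The fallen genes were Scd3, Tmem45b (-0.76 ± 0.13), Wfdc18 (-0.75 ± 0.07), Stmn3 (-0.56 ± 0.09) and Olfr65 (-0.44 ± 0.07). Of these, Wfdc18 alone kept its call whichever array was left out, Olfr65 lay close to the level of silent genes, and the second probe set of Stmn3 differed in the opposite direction.

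A further 6 risen genes, Bicd2, Ippk, Aspn, Nol8, Iars and Fbxw17, lie close together in the gene order of assembly GRCm38.p6, with genes that were not called between them. Only Iars kept its call whichever array was left out. This stretch was singled out after its values were seen. It holds 12 measured genes, of which 9 reached the median level of all probe sets, and all 9 were higher in caNrf2 skin, by 0.19 to 0.59. Of the dimmer 3, Omd differed by 0.38, Ecm2 by -0.04 and 4933433N18Rik by -0.08, while a second, equally dim Ecm2 probe set rose by 0.54 in the fit of all probe sets (adjusted p = 0.0442). The 9 genes had a weighted mean log2 difference of 0.52 ± 0.03 (SE), a 1.43-fold level (95% interval 1.38 to 1.49). This SE and interval take the genes as independent, although they share the same arrays and include the 6 called genes. Computed between arrays, the 95% interval was wider, 1.30 to 1.58-fold. Relative to the control mean, these 9 genes averaged 0.47, 0.47 and 0.62 on the 3 caNrf2 arrays. The 15 genes of that level among the 12 nearest on either side had a median of -0.02 and lay between -0.15 and 0.19.

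**Figure D3:**
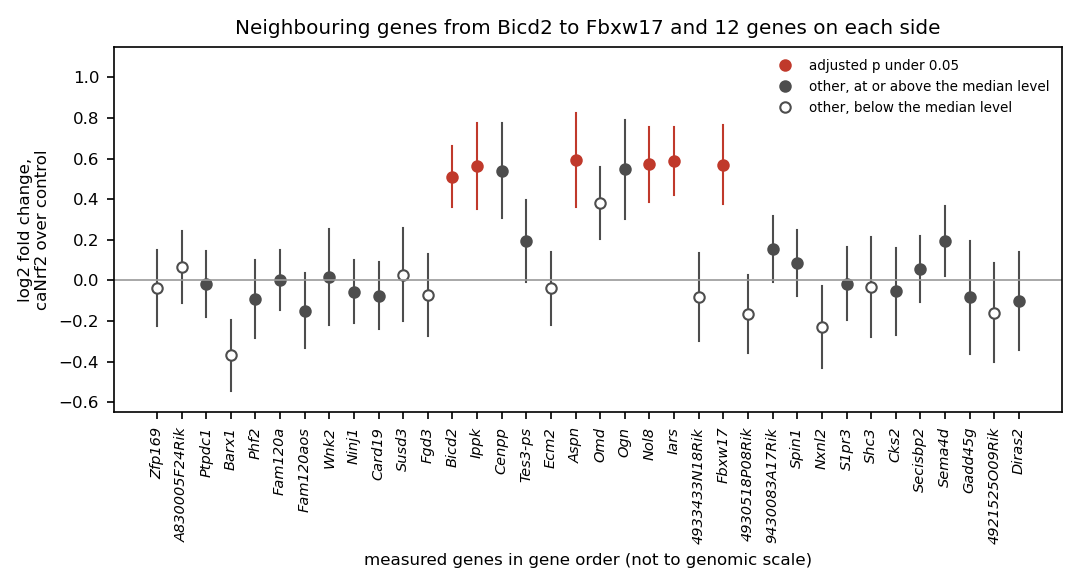
Log2 fold change of caNrf2 over control (points, with 95% intervals) for the 12 measured genes from Bicd2 to Fbxw17 and for 12 genes on each side, in gene order and not to genomic scale. Red points passed an adjusted p of 0.05, and open points lie below the median level of all probe sets; the 6 called genes lie between 0.51 and 0.59.

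Over all 45037 probe sets tested, 102 rose and 6 fell. Without control array 1, 2 or 3 the number of called genes was 41, 43 and 45, and 37 of the 68 genes, 25 of them Nrf2 targets, kept their call whichever array was left out. As a sign of RNA quality, the difference between 3 prime and 5 prime control probe sets shifted by 0.00 for Actb (exact permutation p = 1). For Gapdh it shifted by -0.03, small but without overlap of the groups (exact permutation p = 0.1, the smallest that 3 against 3 arrays can give).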

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

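The values here lie outside the comparison of genes, and no explanation of them was tested. The bacterial and phage hybridisation controls, which are added at a fixed amount before the arrays are hybridised, averaged 0.17 higher (log2) on the caNrf2 arrays, and each caNrf2 array exceeded each control array (exact permutation p = 0.1, the smallest possible). By family the difference was 0.23 for BioB, 0.17 for BioC, 0.16 for BioD and 0.11 for Cre, smaller the brighter the control. The dim Trpn control set went the other way, by -0.10, again without overlap of the groups. The poly-A controls (Dap, Lys, Phe and Thr), which are added to the RNA before labelling, differed by 0.00.

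Of the 108 probe sets called, 16 carry no gene or several genes in the annotation and so took no part in the counts of genes. Among them 14 rose. The 8 with no gene rose by 1.05, 0.88, 0.99, 0.85, 0.85, 0.68, 0.61 and 0.45 on the log2 scale. The 6 with several genes rose by 1.08, 1.85, 1.29, 0.81, 0.47 and 1.27.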

How the results depend on the processing

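Direction was stable for the genes that were followed. These were the 26 genes of the largest rises, the falls and the set named in advance, and 28 others in the text, list members among them. None changed sign under any alternative. Some genes in the text, such as Ecm2, Omd and Ogn, were not followed. Re-normalisation moved the median of all genes by at most 0.01 (log2). The cyclic loess alternative was chosen after the data were seen. Outside the arrays left out, the count of called genes ran from 59 with cyclic loess and 60 with quantile normalisation to 91 with an intensity trend and 94 with array weights, and each normalisation kept at least 59 of the 68 genes. The number changed at least 1.5-fold was 28 instead of 47 when treat tested against a fold of 1.2, where the stricter null makes fewer calls by construction. The number of shifted lists was 0 instead of 18 with an estimated correlation, which allows members to vary together (6 lists at an unadjusted p under 0.05), and 17 on ranks.

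Leaving out 1 array at a time gave 41 to 89 called genes, 39 to 53 changed at least 1.5-fold, 64 to 136 probe sets and 13 to 19 lists. The low counts came from the controls: without control array 1, 2 or 3 there were 41, 43 and 45 called genes and 69, 64 and 67 probe sets. Fits without a caNrf2 array have as few samples. Array weights, lower for arrays that vary more, were 1.28, 1.39 and 1.56 for control arrays 1 to 3. For caNrf2 arrays 1 to 3 they were 0.43, 0.55 and 1.52. Whether this unequal spread gave the low counts without controls was not tested. Without caNrf2 array 1 the 89 genes split into 71 higher and 18 lower, against 63 and 5. The hair follicle keratins and shaft list, with a median of -0.06, had a median of -0.24 without caNrf2 replicate 1, where camera called it downward. It reversed to a median of 0.0924 without caNrf2 replicate 3, where camera called it upward. The cause was not tested.

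Over all alternatives, 8 calls were gained and 30 lost among the genes of the largest rises, the falls and the set named in advance. Among the 28 others 6 were gained and 40 lost. Nfe2l2 passed with median centring, the filter, array weights and the trend (lowest adjusted p = 0.0171). Slc7a11 passed with the mean of its probe sets, the trend, array weights and without caNrf2 replicate 1. Scd3 (0.0550) and Stmn3 (0.467) lost their calls with the mean of probe sets, Slpi with quantile normalisation, cyclic loess and array weights, and Olfr65 with the replicate block (0.0665).

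Replicate numbers are not said in the labels to mark a shared batch. Deviations of same-numbered samples correlated at -0.20, -0.03 and 0.04, and those of differently numbered samples between -0.16 and 0.19. These values gave no sign of pairing, but they cannot show how the animals were handled. With the number as a replicate block there were 61 called genes, 57 of them shared with the fit without it, 46 changed at least 1.5-fold, 97 probe sets and 19 lists. Signal over background limits genes near the Y-linked level, Gsta3 in control skin and Olfr65 among them.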

Other observations

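The tests of keratinocyte share, of the share of other tissue, of members varying together, of the stretch from Bicd2 to Fbxw17 and of the synthetases without Iars were chosen after the results were seen, as was the grouping of genes by symbol. The hair follicle programme varied among the caNrf2 animals. Relative to the control mean, the follicle keratins and shaft genes averaged 0.21, 0.00 and -0.43 on the 3 caNrf2 arrays, and between -0.02 and 0.02 on the control arrays. Melanocyte markers followed the same order, at 0.07, 0.01 and -0.27, and sebaceous and erythroid markers were also lowest on caNrf2 array 3 (-0.23 and -0.35). Grouped by symbol alone, 11 of 296 gene families passed camera at the preset correlation and none with an estimated correlation (adjusted p = 0.968). The aldehyde dehydrogenase family (20 genes, median 0.07), the Abcc transporters (10 genes, 0.02) and the proteasome families Psmd (14 genes, 0.07) and Psma (8 genes, 0.09) were shifted upward, but the proteasome family Psmb (11 genes, -0.02) was not. The other 7 were lower, among them the chemokine receptors Ccr (10 genes, -0.13), none of which was higher in caNrf2 skin. The families Ccr, Olfr, Dnah and Nkx had mean levels of 4.92, 4.19, 4.77 and 5.35 (log2), below the 6.34 of the median probe set.

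The rise of 63 genes is the first pattern. A scaling difference between arrays would raise other genes of the same level. Among genes that were not called, the 2858 nearest in level had a median of 0.01 (0.009421), against 0.67 for the risen genes. The risen genes thus stood apart from others of their level. This cannot decide about scaling before normalisation, since quantile normalisation holds the typical gene near no difference. A larger share of keratinocytes would raise the basal markers alike, and these lay 0.61 below the risen genes (95% bootstrap interval over genes, not mice, 0.53 to 0.81). A gap was fixed in advance, since the risen genes had been picked for their rise, so it is no test. The values do show that no basal marker rose by more than 0.15, against 0.40 or more for each risen gene. Only 1 of the 10 possible splits of the 6 arrays, the real one, gave 68 genes, 47 genes at 1.5-fold or 108 probe sets, and the other splits gave at most 0, 0 and 4, but 10 splits are too few for a share under 0.05. Active Nrf2 may account for the rise of its known targets, and for the other risen genes this was not tested.

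The small shifts of 13 lists outside the Nrf2 targets are the second pattern. After quantile normalisation 8 of the 13 kept their call and after cyclic loess 10, so those calls did not rest only on differences that these steps remove. This cannot decide about intensity-dependent differences, since RMA had already normalised by quantiles and the same test had picked the lists. With the filter on low values only 5 of 11 kept their call. Level-matched random lists had medians of -0.06, -0.04, -0.02 and 0.01 for the neutrophil, T cell, Langerhans and adipocyte lists. Of the 13 lists 9 lay outside 95% of random lists of the same levels, but this cannot decide. The 13 had been picked for a shift, and the random lists ignore that members vary together. Lists that were not called, such as the endothelial and melanocyte lists, lay outside too. The hybridisation controls also differed between the groups, by 0.11 for Cre to 0.23 for BioB. A lower share of all other tissue remains open: 10 of the 12 lists of other cell types had a negative median and 0 differed from their common mean of -0.07, whose interval between arrays, -0.16 to 0.02, includes no change. Members that vary together between mice remain possible: 0 of the 13 lists passed with an estimated correlation, but this test also lost the Nrf2 lists. Fry, testing for 1 direction, called 4 lists, all of Nrf2 targets, and so none of these 13. The lowest adjusted p among them was 0.0637, for the aryl hydrocarbon receptor list. Testing either direction, fry called that list and those of hypoxia and glycolysis, barrier lipids, and proteases and inhibitors (adjusted p from 0.000112 to 0.0266). The real split called 18 lists and the highest of the other splits called 15, and 10 splits cannot give a share under 0.05, so these shifts may be differences between single mice.

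The stretch of neighbouring genes from Bicd2 to Fbxw17 is the third pattern, a hypothesis found and tested on the same data. Chance clustering is argued against, since 6 called genes of different families within 15 measured neighbours arose in none of 10000 random placements of the 68 genes, which gave at most 4 (permutation p = 1e-04, the smallest they can give). Strain variants under single probes are argued against because all 14 probe sets at or above the median level other than the 6 behind the calls were higher, 5 of them of genes not called, and a rise limited to keratinocytes because the fibroblast genes Aspn and Ogn differed by 0.55 or more on the probe sets used, and by 0.48 on a second Aspn probe set. An extra copy of the segment in the caNrf2 mice is a candidate explanation: 1 copy beside the usual pair would give 0.58 on the log2 scale, which lies outside the gene-level interval (1.38 to 1.49-fold) but inside the interval between arrays (0.38 to 0.66, mean 0.52), and the 6 segment genes that were not called still had a median of 0.29 (4933433N18Rik was not higher, and the probe sets of Ecm2 disagreed), above the -0.13 to 0.08 of level-matched genes. Whether such a copy would come with the transgene or from a parental strain was not tested, and linkage of other genes to the transgene stays open: of 36 called genes outside the lists 8 had a called neighbour of another family within 20 measured genes (random sets, permutation p = 0.121), but 6 of these are the stretch itself, and of the other 30 genes 2 had one, against a median of 3 in random sets.

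Among 11634 runs of 6 well measured neighbours the highest median, 0.57, lay in this stretch, and the next highest outside it, 0.32, at the Gstm cluster, while the lowest was -0.23. Iars, the isoleucyl-tRNA synthetase of the stretch, prompted a check of its family. The 16 other cytoplasmic aminoacyl-tRNA synthetases had a median of 0.05 (0.04616, SD 0.06) and 13 were higher, a shift that camera called at the preset correlation but not with an estimated correlation. The highest reached 0.18, far below the 0.59 of Iars, so a rise of all synthetases does not account for the size of its rise.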
